A study of Homo sapiens with 16 samples.

How the data were processed

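Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The cells were MCF7, an established oestrogen receptor-positive breast cancer line, and LTED, a derivative of MCF7 kept without oestrogen for 1 year, per the labels. MCF7 was grown with 10 nM oestradiol (E2) or starved of it for 2 days. Each culture was sorted by FACS on CD44, a hyaluronan receptor on the cell surface, and 50000 cells per CD44high or CD44low fraction were used, per the labels' protocols.

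The authors deposited 1 peak list per library, each peak with a position and a score, so peaks had been called in each library on its own. The deposited score has no named unit. Its floor of 50 is what minus 10 log10 of a p-value of 1e-05 would give, which is the form and the default limit of the peak caller named in the notes. Per the submitters' processing notes, the tools were Trim Galore 0.4.0, Bowtie2 2.2.9, SAMtools 1.3.1 and MACS 1.4.1. The notes name the builds mm10 and hg38, and the contig names in the lists are those of hg38, so coordinates are given as hg38 (1-based). Whether reads were shifted for the transposase, filtered for duplicates or thinned to 1 depth was not given in the sources used here. The lists carry no read counts or signal, so sequencing depth is unknown. A region with no peak is one where the caller's limit was not reached, which is not the same as closed chromatin, and a list grows with depth, quality and copy number. No interval from counting error can be given.

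Peaks on chromosomes 1 to 22 and X were used, 541718 of 542554, and the other 836 were left out. The scores rank peaks within a list. Peaks of all 16 lists were merged into 90956 union regions (1 bp overlap), and a region was present in a library if a peak overlapped it. Planned comparisons were CD44high against CD44low over all conditions, starved MCF7 against MCF7 with E2, LTED against MCF7 with E2, and LTED against starved MCF7. Fisher's exact test (two-sided) was run per region on the number of libraries with a peak. It was adjusted by Benjamini-Hochberg over the regions whose total allowed a p at or under 0.05, with a threshold of 0.05. All-or-none regions, with a peak in every library of one arm and in none of the other, were counted beside it. Values per library were compared by exact two-sided permutation of the arm labels within CD44 fraction, or within condition for the CD44 comparison. That gave 2400 permutations for CD44, 400 for LTED against MCF7 with E2 and 100 for each comparison with starved cells. The similarity of libraries (Jaccard index, shared over union base pairs, with the computation checked against bedtools 2.31.1) was tested one-sided in the same way.

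The annotation was NCBI RefSeq for GRCh38.p14, with 19974 protein-coding genes, each with a start, an end and no strand. A region belonged to the nearest gene body within 100 kb, and a gene end means a position within 1 kb of either end of a gene, since the transcription start could not be told from the other end. Gene-end shares and gene list shares were taken on equal-length lists, each reduced to its 12985 highest-scoring peaks, the length of the shortest list. Of the 345 genes on 20 fixed lists, 345 matched the annotation. The lists were oestrogen receptor targets, luminal identity, basal and mesenchymal genes, stem and progenitor genes, AP-1 members, YAP and TEAD targets, cholesterol synthesis, dormancy and quiescence, proliferation, growth factor receptor signalling, interferon response, NF-kB response, hypoxia, Notch and Wnt, TGF-beta and BMP, steroid metabolism, markers of blood, fibroblast and endothelial cells, and housekeeping genes. List shares were adjusted over the 20 lists. List members with an all-or-none region were also counted against 10000 random gene sets matched on the number of tested regions. Motif shares, planned for 24 motifs, were not analysed here, since no genome sequence was used.

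The groups, tests, lists and alternatives named as planned were chosen before the data were examined. The alternatives were a score of at least 100, equal-length lists, 50% of the region covered, 500 bp bins, a test stratified by fraction or condition, a replicate block, at most 1 exception to the all-or-none rule, a gene-end window of 2.5 kb, genes within 20 kb, and leaving out libraries. After the data were seen, LTED against all MCF7 libraries, oestrogen-deprived cells (LTED and starved MCF7) against MCF7 with E2, and the removal of 39 windows of 1 Mb in which the peaks of any library covered at least 20% were added. Lists without those windows were reduced to 10078 peaks, and in a further setting each peak was trimmed to 500 bp. Leaving out GREB1 or chromosome 15 was added as well.

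Named genes were, per comparison and direction, the 10 protein-coding genes with the most regions past the test (ties by distance to a gene end). Where no region passed, the same rule was applied to the all-or-none regions, and this is stated. To these were added list members with such a region, and CD44, CD24, ESR1, TFF1, GREB1, PGR, FOXA1, GATA3, KRT80, CYP19A1, SQLE and CDKN2A in any case. The region test was tested on simulated data with 200 or 2000 regions made all-or-none, and the share recovered is given with each comparison. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.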

Results

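ATAC-seq peak lists were available for 16 libraries of sorted MCF7 and LTED breast cancer cells. There were 3 CD44high and 3 CD44low libraries of LTED, 3 and 3 of MCF7 with E2, and 2 and 2 of starved MCF7. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. If the CD44high and CD44low libraries of one number came from one culture, the condition comparisons would rest on fewer independent units than the number of libraries.

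The lists held 12985 to 49184 peaks. Starved MCF7 had 39736 ± 7176 peaks (SD, n = 4), MCF7 with E2 29685 ± 4531 (n = 6) and LTED 34111 ± 14757 (n = 6). The 10051 more peaks of starved cells over E2 cells passed an exact two-sided permutation test (p = 0.03). Their peaks were also wider, with a median of 1333 ± 27.6 bp against 1057 ± 42.5 bp, and covered 67.9 ± 11.7 Mb against 38.5 ± 7.67 Mb (exact permutation p = 0.01 for each, the smallest that 100 permutations can give). The shortest LTED lists were those of replicate 2, with 12985 peaks in CD44high and 18290 in CD44low. CD44high (34788 ± 12405, n = 8) and CD44low (32927 ± 8435, n = 8) did not differ in number (exact permutation p = 0.696). Of the 90956 union regions, 6725 had a peak in all 16 libraries and 29869 in 1 library.

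**Figure D1:**
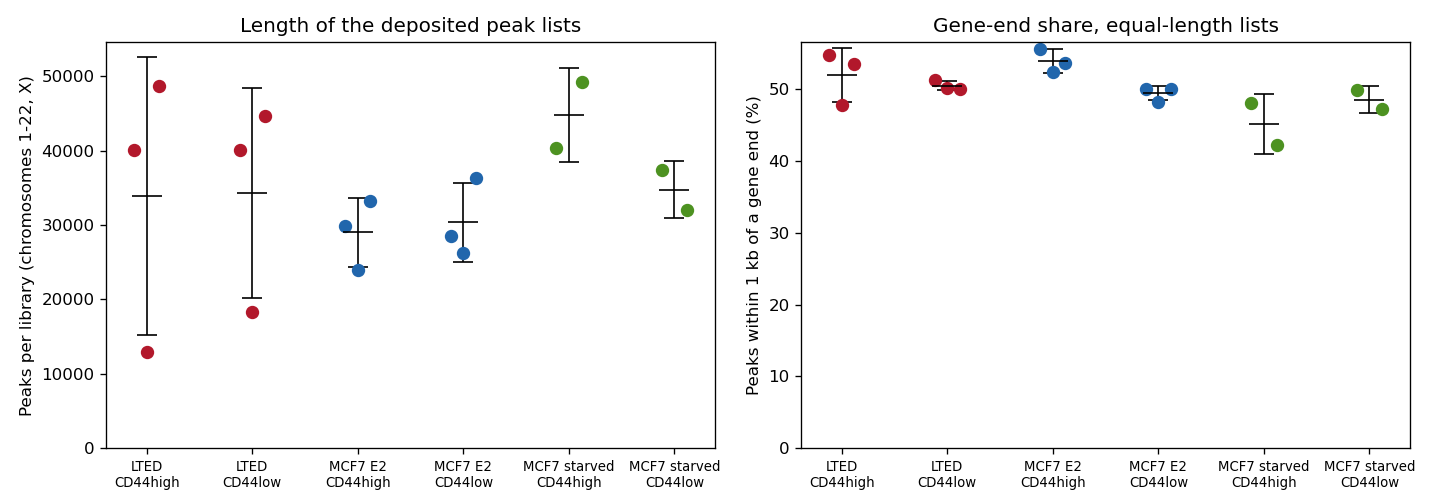
Peaks per library (left, number on chromosomes 1 to 22 and X) and share of peaks within 1 kb of a gene end in equal-length lists (right, percent), by group. Points are libraries and black bars the mean ± SD; starved MCF7 held 39736 peaks on average against 29685 with E2, and its gene-end share was 46.8% against 51.6%.

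A gene-end peak of FOXA1 (14:37589995-37605028) and of the progesterone receptor gene PGR (11:101126623-101130426) was present in 16 of 16 libraries. The merged region at GATA3 (10:8044406-8056547) had a peak in 16 of 16 as well. Peaks within 1 kb of the lower-coordinate end of GATA3 were found in only 11 libraries, and of its upper-coordinate end in 7. The 11 were 3 CD44high and 3 CD44low libraries of LTED, 1 and 1 with E2, and 2 and 1 starved. SQLE (8:124996809-125002010), which encodes squalene epoxidase of cholesterol synthesis, also had a gene-end peak in 16 of 16 libraries. CD24 is a surface glycoprotein gene often sorted beside CD44, and its merged region (6:106972309-106976203) had a peak in 16 of 16. Its gene-end peak was found in 9 libraries, 6 CD44high and 3 CD44low (Fisher's exact two-sided p = 0.315, unadjusted). KRT80, a keratin gene, had a gene-end peak (12:52190675-52193241) in 15 of 16 libraries. On equal-length lists 3 CD44high and 2 CD44low LTED libraries, 0 E2 libraries and 1 starved CD44low library had it. The Fisher's exact two-sided p for LTED against E2 was 0.0152 (unadjusted). The merged region at an end of the oestrogen receptor gene ESR1 (6:151657438-151659797) had a peak in 6 of 6 LTED, 3 of 6 E2 and 2 of 4 starved libraries. The peak itself came within 1 kb of that gene end in only 3 libraries. These were 1 LTED CD44high, 1 LTED CD44low and 1 starved CD44high library. TFF1 encodes a secreted trefoil peptide induced by oestrogen. Its merged region (21:42362605-42368204) had a peak in 3 of 6 LTED, 6 of 6 E2 and 4 of 4 starved libraries. A peak within 1 kb of its upper-coordinate end was found in 1 LTED, 3 and 3 E2 and 2 and 2 starved libraries. The Fisher's exact two-sided p for LTED against E2 was 0.0152 (unadjusted). At its lower-coordinate end 0 LTED libraries had one, against 2 E2 CD44high and 2 and 2 starved libraries. For LTED against starved the Fisher's exact p was 0.00476 (unadjusted). At CDKN2A, the p16 tumour suppressor gene, a gene-end peak (9:21993680-21996215) was present in 5 of 6 LTED libraries and in 0 of 10 MCF7 libraries. Markers of other cell types were mostly without gene-end peaks. Of 10 blood cell markers a library held 0 to 5, of 11 fibroblast markers 1 to 4 and of 7 endothelial markers 1 to 3.

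The sort on CD44 asked whether cells with much surface CD44 differ in open chromatin from cells with little. Peaks near oestrogen receptor target genes, a list of 28 that includes GREB1, TFF1 and PGR, took a smaller share of the list in CD44high cells. The share was 0.149% ± 0.0273 in CD44high (SD, n = 8) and 0.193% ± 0.0486 in CD44low (n = 8), a difference of -0.0443 percentage points (exact two-sided permutation p = 0.0025). Adjusted over the 20 lists the p was 0.05, at the threshold (exact permutation test, n = 8 each). In MCF7 with E2 the means were 0.177% ± 0.0133 in CD44high and 0.239% ± 0.0308 in CD44low (n = 3 each). In LTED they were 0.133% ± 0.00445 and 0.167% ± 0.0489 (n = 3 each), and in starved MCF7 0.131% ± 0.0327 and 0.166% ± 0.00545 (n = 2 each). The gap within LTED and within starved cells was near or under the larger of the 2 SDs. Without GREB1 the share was 0.134% in CD44high against 0.172% in CD44low (exact permutation p = 0.00333, a test added later).

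The other 19 lists did not pass. Luminal identity genes came nearest, at 0.269% ± 0.0320 in CD44high and 0.302% ± 0.0361 in CD44low (exact permutation p = 0.0283, adjusted 0.283, n = 8 each). Stem and progenitor genes, a list that holds CD44, CD24 and SOX9, differed by 0.00193 percentage points (exact permutation test, adjusted p = 1). CD44high minus CD44low was 0.00289 points for AP-1 members, 0.00385 for YAP and TEAD targets, -0.0106 for cholesterol synthesis, 0.0125 for dormancy and quiescence, -0.00289 for proliferation and -0.0125 for growth factor receptor signalling. It was 0.00289 for interferon response, 0.00578 for NF-kB response, 0.00193 for hypoxia, -0.00481 for Notch and Wnt, 0.00866 for TGF-beta and BMP and -0.00866 for housekeeping genes. Blood, fibroblast and endothelial marker lists had adjusted p-values of 1, 0.922 and 1 (exact permutation test). With all deposited peaks the oestrogen receptor target list passed with an adjusted p of 0.0167. It did not pass with the 39 dense windows left out, where the difference was -0.0558 points (exact permutation p = 0.0167, adjusted 0.167), 0 lists passed when genes had to lie within 20 kb, and 0 passed without any 1 of 8 libraries, namely the 3 LTED CD44high, the 2 starved CD44high and the 3 E2 CD44low libraries.

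**Figure D2:**
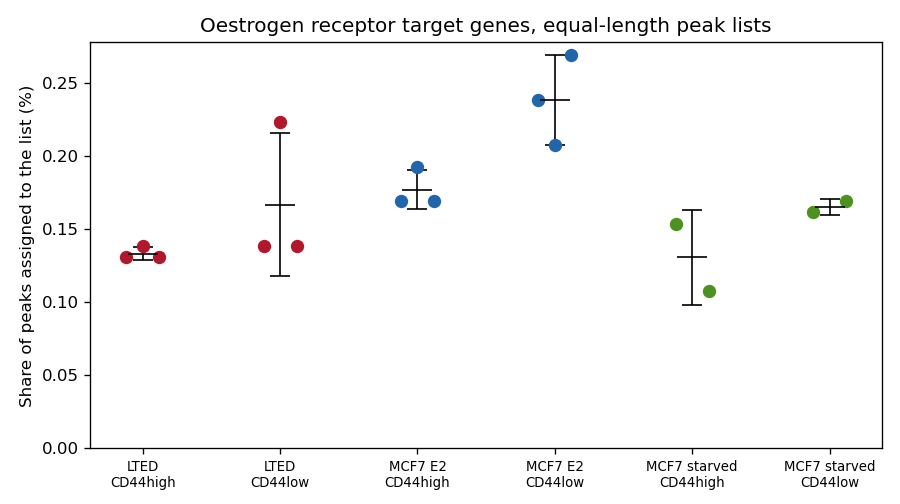
Share of each library's 12985 highest-scoring peaks (percent) assigned to 28 oestrogen receptor target genes, by group. Points are libraries and black bars the mean ± SD; group means run from 0.131% in starved CD44high cells to 0.239% in E2 CD44low cells.

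No single region separated the CD44 fractions. At the start of CD44 itself (11:35138327-35140503), 6 of 8 CD44high and 3 of 8 CD44low libraries had a peak (Fisher's exact two-sided p = 0.315), and a region upstream of the gene (11:35081934-35083544) had one in 7 and 8. Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 20122 tested regions, with 213 at an unadjusted p of at most 0.05, and 0 regions were all-or-none. On equal-length lists it called 0, with 79 at that unadjusted level. Regions of list members gave 0 calls adjusted over the list alone. In the simulation, 100% of 200 all-or-none regions were recovered for this comparison. The gene-end share was 50.9% ± 4.59 in CD44high and 49.6% ± 1.26 in CD44low (exact permutation p = 0.344, n = 8 each), but without replicate 2 of starved CD44high the difference was 2.62 points (exact permutation p = 0.0383). Similarity within a fraction did not pass against similarity between fractions (Jaccard index 0.404 within, 0.409 between, exact one-sided p = 0.343).

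Within conditions the fractions could only be counted, since 3 against 3 or 2 against 2 libraries cannot give a region a p at or under the threshold. In MCF7 with E2, 334 regions were open in every CD44high library alone and 156 in every CD44low library alone. In LTED the counts were 24 and 56, and in starved MCF7 4520 and 665. Starved CD44high lists were also longer, with 44743.5 peaks on average against 34728.5 in starved CD44low. On equal-length lists the counts were 177 and 73 in E2 cells, 89 and 138 in LTED and 737 and 522 in starved cells. With all deposited peaks, gene ends made up 30.2% of the CD44high-only regions in E2 cells and 12.8% of the CD44low-only ones, against 16.1% of all regions. In starved cells the shares were 6.73% and 21.4%. These shares were not tested. The totals of 80 regions in LTED, 490 in E2 cells and 5185 in starved cells were 159 to 2331, 989 to 3049 and 10656 to 16733 without any 1 of the libraries of that condition. CD44high-only regions of E2 and starved cells had 21 in common, where independent lists would share 16.6, and 4 in opposite fractions. CD44low-only regions had 3 in common, where independent lists would share 1.14, and 10 opposite. On equal-length lists CD44high-only regions had 8 in common, where independent lists would share 4.87, and 7 opposite. No value for independent lists was computed for the opposite counts, which grow with list length, so they do not show opposed effects. CD44high minus CD44low in gene-end share was 1.52 points in LTED and 4.38 in MCF7 with E2, and the difference of -2.86 points did not pass (exact two-sided permutation p = 0.265). In starved MCF7 the CD44high share was the lower one, 45.1% against 48.5% (means, n = 2 each, not tested).

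Removal of E2 for 2 days asked which open chromatin in MCF7 follows the hormone. GREB1, an oestrogen-induced cofactor gene of the receptor, had peaks inside the gene in MCF7 with E2 that starved MCF7 lacked. The regions 2:11498040-11499484 and 2:11538832-11540628 had a peak in 6 of 6 E2 libraries and 0 of 4 starved libraries, while its gene-end region (2:11482132-11484370) had one in 6 and 4. On equal-length lists they had a peak in 1 and 4 of 6 E2 libraries, and 2:11530539-11531875 had one in 6 of 6 and 0 of 4, though with all deposited peaks it was open in 4 of 4 starved libraries too. Oestrogen receptor targets took 0.148% ± 0.0277 of peaks in starved cells (n = 4) and 0.208% ± 0.0399 with E2 (n = 6), lower by exact permutation test (p = 0.01). Also lower were AP-1 members, the FOS and JUN family genes, at 0.0847% ± 0.00629 against 0.110% ± 0.00795, and hypoxia genes at 0.0751% ± 0.00737 against 0.0988% ± 0.00757. Dormancy and quiescence genes took a larger share, 0.237% ± 0.0238 against 0.171% ± 0.0250. On equal-length lists TGFB2, a growth-inhibiting cytokine gene of that list, had 2 regions and FOXO1, a forkhead factor gene, 1 region open in every starved library and in no E2 library.

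Each of these 4 lists had an exact two-sided p of 0.01, the smallest that 100 permutations can give, and an adjusted p of 0.05, at the threshold. Fibroblast markers stood at 0.0481% ± 0.0132 in starved cells and 0.0270% ± 0.00422 with E2, and endothelial markers at 0.0135% ± 0.00737 and 0.0565% ± 0.0159 (exact permutation test, adjusted p = 0.0667 for each). With all deposited peaks, with genes within 20 kb, or without any 1 of the 10 libraries, 0 of the 20 lists passed. With all deposited peaks the difference was larger for oestrogen receptor targets (-0.0823 points, against -0.0597). It was smaller for AP-1 members (-0.0113, against -0.0257), hypoxia genes (-0.0118, against -0.0237) and dormancy genes (0.0238, against 0.0661). Leaving out a library leaves fewer permutations, so the smallest p is larger. Without dense windows, AP-1 members, dormancy genes, cholesterol synthesis genes (-0.0364 points) and endothelial markers (-0.0562 points) passed (adjusted p = 0.05, exact permutation test). Oestrogen receptor targets (-0.0728 points, against -0.0597 with those windows) and hypoxia genes (-0.0289 against -0.0237) then had an adjusted p of 0.0571 (exact permutation test). Without GREB1 the oestrogen receptor target share was 0.141% ± 0.0221 against 0.177% ± 0.0387 (exact permutation p = 0.07), a test added later.

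Open regions separated starved from E2 cells mostly one way in the deposited lists. There were 1039 regions with a peak in all 4 starved and no E2 library and 46 the other way. Their total of 1085 was 1647 without replicate 1 and 2212 without replicate 2 of starved CD44low. The genes with most starved-only regions were VPS13B with 5, and HTR2A, PLXDC2, PRKCA, SYNPR, CTNNA3 and PDE1C with 4 each, followed by RFTN1, ZNF281 and GFRA1 with 3 each. HTR2A encodes a serotonin receptor, PRKCA a protein kinase C and GFRA1 the GDNF co-receptor. Members of the fixed lists were MYC with 2 regions, and ATF3, BATF, KRT8, VEGFA, FOXO1 and FOXO3 among those with 1. At SQLE the upstream region 8:124990091-124991605 had a peak in 4 of 4 starved libraries and in 0 of the 12 others. E2-only regions were led by GREB1 with 2, followed with 1 each by IFFO2, SPDYA, ADRA2C, LOC124900940, OVOL1, E4F1, CASC3, SNAPC2 and LDLR, the low-density lipoprotein receptor gene. AREG and NRG1, genes of ligands of the EGF receptor family, had 1 each.

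None of these regions passed the test. Against random gene sets, oestrogen receptor targets came nearest among E2-only regions (permutation p = 0.0064, one-sided, from 10000 random sets, adjusted 0.128). Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 21535 regions, with 4577 at an unadjusted p of at most 0.05, and the smallest adjusted p was 0.0945. In the simulation it recovered 0% of 2000 all-or-none regions for this comparison. Adjusted over the list alone, 8 regions of list members were called in starved cells (ATF3, BATF, SQLE, HSD17B7, MYC, NFKB1 and NFKBIA) and 1 in E2 cells (LDLR), against 0 over all regions. Of these genes HSD17B7 alone was also called on equal-length lists, where the other calls over the list alone were CELSR2, CLDN4, TFAP2C, TGFB2, FOXO1 and YWHAZ in starved cells and EGR3, GREB1, SPDEF and SPI1 in E2 cells. On equal-length lists 0 of 7302 regions were called, with 1536 at that unadjusted level, and the all-or-none counts were 309 and 96, so the starved share of them was 76.3% in place of 95.8%. Gene ends made up 2.89% of starved-only regions, 28.3% of E2-only regions and 13.2% of all tested ones. The gene-end share of whole equal-length lists was 46.8% ± 3.30 in starved cells (n = 4) and 51.6% ± 2.70 with E2 (n = 6), a difference of -4.81 points (exact two-sided permutation p = 0.02). Without any 1 of the 3 E2 CD44high libraries that p was 0.0833. Libraries of one condition were more alike than libraries of different conditions (Jaccard index 0.488 within, 0.396 between, exact one-sided p = 0.01, the smallest possible).

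**Figure D3:**
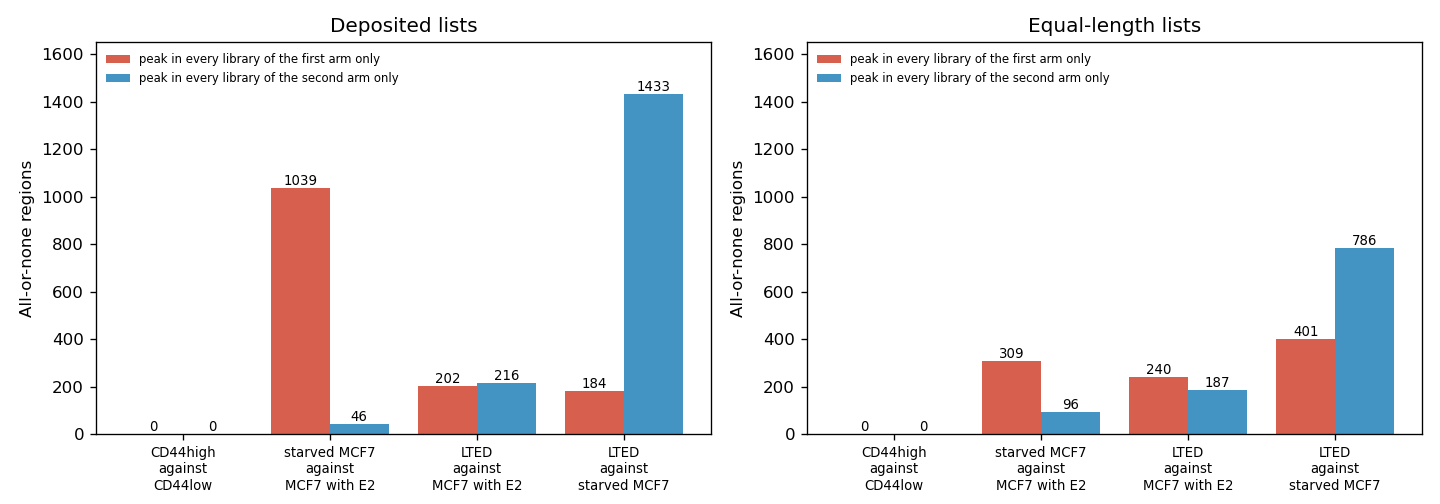
Number of all-or-none regions in 4 comparisons, for deposited lists (left) and equal-length lists (right). Red bars count regions with a peak in every library of the first-named arm and none of the second, blue bars the reverse; starved against E2 gives 1039 and 46 with deposited lists and 309 and 96 with equal-length lists.

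LTED against MCF7 with E2 asked what long oestrogen deprivation leaves different. LTED carried a block of dense peaks on chromosome 15. Of 202 regions with a peak in all 6 LTED and no E2 library, 151 lay between 15:49000001 and 15:55000000, from 49448562 to 54251827. LTED peaks covered 9.83% to 65.6% of that segment, against 0.705% to 2.86% in the 10 MCF7 libraries. The genes with most LTED-only regions were all there, WDR72 with 19, UNC13C 13, ATP8B4 11, FAM227B 10, MYO5A 8, DTWD1, TNFAIP8L3 and DMXL2 6 each, and GABPB1 and CYP19A1 5 each. CYP19A1 encodes aromatase, which makes oestrogens from androgens.

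**Figure D4:**
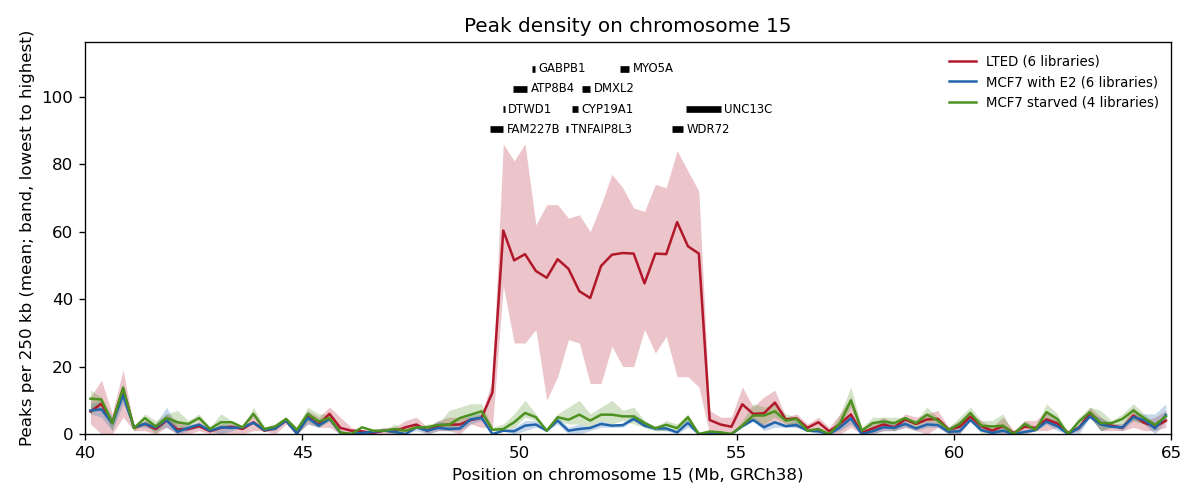
Peaks per 250 kb along chromosome 15 (hg38, Mb), mean of each condition with a band from the lowest to the highest library, and the genes with most LTED-only regions as black bars. The LTED libraries rise above all MCF7 libraries over a block whose LTED-only regions run from 49448562 to 54251827.

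The 216 E2-only regions were spread over the genome. LAMA1, HPGD, ZFAT, SERTAD4, LOC107985876, TNS3 and TENM3 had 2 each, and CHRM3, SOX11 and AGBL3 1 each. LAMA1 encodes a laminin chain and HPGD a prostaglandin dehydrogenase. Of the oestrogen receptor targets MYB, AREG and TFF3 had 1 each, as did NRG1. The list's share was 0.150% ± 0.0360 in LTED and 0.208% ± 0.0399 with E2 (n = 6 each, exact permutation p = 0.01, adjusted 0.05). Basal and mesenchymal genes fell from 0.146% ± 0.0162 with E2 to 0.0873% ± 0.0274 in LTED and AP-1 members from 0.110% ± 0.00795 to 0.0834% ± 0.00580 (exact permutation p = 0.005, the smallest possible, adjusted 0.0333 for each, n = 6 each). Steroid metabolism genes rose from 0.0385% ± 0.00487 to 0.187% ± 0.0287 (exact permutation test, adjusted p = 0.0333), and CYP19A1, inside the chromosome 15 block, was the only member with LTED-only regions. Without dense windows, steroid metabolism differed by -0.00331 points and oestrogen receptor targets by -0.0645 points (exact permutation test, adjusted p = 1 and 0.2). NF-kB response genes stood at 0.0655% ± 0.0106 against 0.0424% ± 0.00943, short of the threshold (exact permutation test, adjusted p = 0.06). Of the 20 lists 4 passed, and 2 without replicate 1 or without replicate 2 of E2 CD44low. With all deposited peaks 8 passed, among them NF-kB response (0.0211 points, exact permutation test, adjusted p = 0.05), while AP-1 members did not (-0.0174 points, exact permutation test, adjusted p = 0.08).

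Single regions of ESR1, GATA3 and FOXA1 differed, in both directions, none of them past the adjusted test on the deposited lists. Within ESR1, 6:151689157-151690798 had a peak in 6 of 6 LTED, 2 of 6 E2 and 0 of 4 starved libraries. At the end of GATA3, 10:8070164-8074596 had one in 5, 0 and 0, and beside FOXA1, 14:37574728-37576322 had one in 5, 0 and 2. Beyond GATA3, 10:8102512-8104044 went the other way, with 0, 5 and 2. Some MCF7 libraries did have a peak within 1 kb of the upper-coordinate end of GATA3. The counts for CD44high and CD44low were 3 and 1 in LTED, 1 and 1 with E2, and 0 and 1 in starved cells. On equal-length lists the ESR1 region had a peak in 2 of 6 LTED libraries, the GATA3 gene-end region in 1 of 6 and the FOXA1 region in none. At the lower-coordinate end of GATA3, 3 CD44high and 3 CD44low LTED libraries then had a peak within 1 kb, and 0 MCF7 libraries did. The Fisher's exact two-sided p was 0.00216 against E2 and 0.00476 against starved cells (unadjusted). With all deposited peaks that end had one in 11 libraries, MCF7 libraries among them. The GREB1 regions without a starved peak had one in 5 and 6 of 6 LTED libraries. At CDKN2A the regions of CDKN2A and its neighbour CDKN2B (9:22008260-22009956) each had a peak in 5 of 6 LTED and 0 of 10 MCF7 libraries (Fisher's exact p = 0.00137 against all MCF7, unadjusted and chosen after the values were seen).

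**Figure D5:**
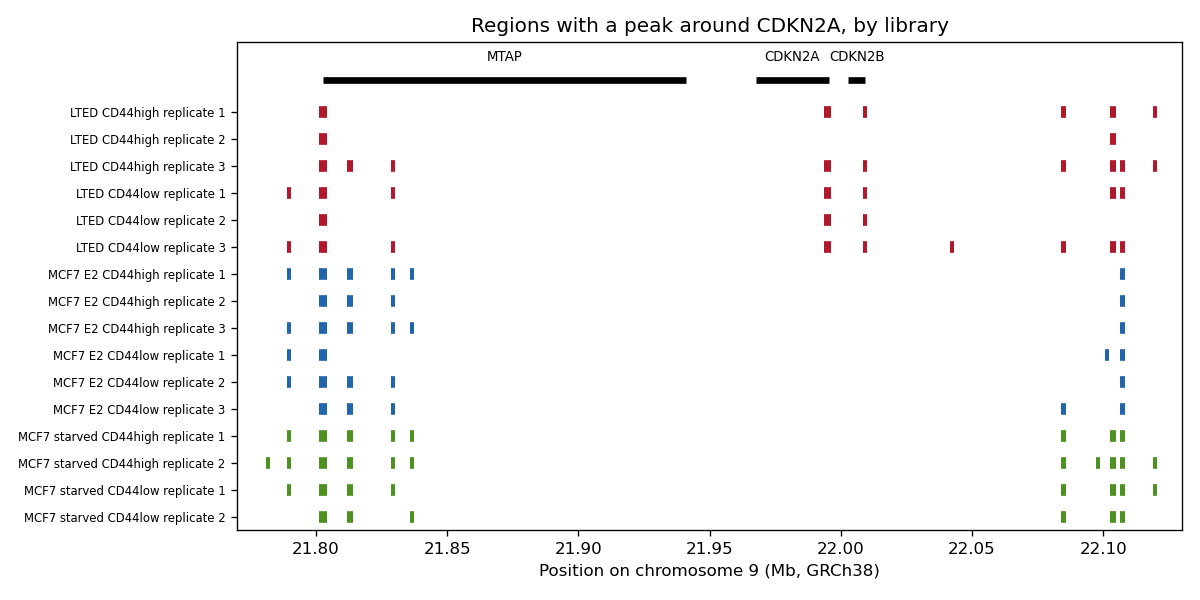
Regions with a peak around CDKN2A on chromosome 9 (hg38, Mb), a line per library, with MTAP, CDKN2A and CDKN2B as black bars. The regions at CDKN2A and CDKN2B are marked in 5 of 6 LTED libraries and in 0 of 10 MCF7 libraries, while the gene-end region of MTAP is marked in all 16.

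On the deposited lists Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 10400 regions, with 1361 at an unadjusted p of at most 0.05 and a smallest adjusted p of 0.0539. In the simulation it recovered 0% of 200 and 100% of 2000 all-or-none regions. Without replicate 2 of LTED CD44high, the shortest list, it called 768 regions, and without both LTED libraries of replicate 2 it called 2808 regions open in LTED and 220 with E2. On equal-length lists it called 595 regions in LTED and 504 with E2. In LTED these were led by WDR72 with 22, UNC13C with 16 and ATP8B4 with 15, and 193 of the 595 lay on chromosome 15. List members called in LTED included CYP19A1 with 7, IL6 with 3, AGR2 with 2, and TBX3, SOX9, ID1, IGF1R and HSD17B7 with 1 each. Genes called with E2 were led by SPDEF, a luminal transcription factor gene, RHOBTB1, ARID5B, TNS3, SUGCT, ESRRG and GSE1 with 3 each. List members called with E2 included GREB1, PDZK1, AREG and STC2 of the oestrogen receptor targets, FOSL2, LGR5, FN1, TGFB2, JAG1 and AXIN2. Adjusted over the list alone, 19 list regions were called in LTED and 13 with E2, against 34 over all regions on equal-length lists (a region of a gene on more than 1 list counted once). On the deposited lists the counts over the list alone were 8 and 7. AGR2, IL6 and ID1 lie in windows of 1 Mb where every LTED library had more peaks than every MCF7 library, counted on equal-length lists. TGFB2 and TFF3 lie in windows where every one had fewer. On equal-length lists, 295 of the 595 calls in LTED lay in windows with more peaks in LTED. Of the 504 calls with E2, 84 lay in windows with fewer.

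The gene-end share was 51.2% ± 2.54 in LTED and 51.6% ± 2.70 with E2 (n = 6 each), with no difference past the spread (exact two-sided permutation p = 0.845). The difference of -0.400 points was 0.832 with dense windows left out (exact p = 0.45), 0.298 without replicate 2 of LTED CD44high and 0.395 without replicate 1 of E2 CD44high. Libraries of one condition were more alike than libraries of different conditions (Jaccard index 0.439 within, 0.380 between, exact one-sided p = 0.02). That p was 0.055 without replicate 2 of E2 CD44high or without replicate 1 or 3 of E2 CD44low.

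LTED against starved MCF7 set long against short deprivation. Dormancy and quiescence genes took 0.142% ± 0.0106 of peaks in LTED (n = 6) and 0.237% ± 0.0238 in starved cells (n = 4), YAP and TEAD targets 0.117% ± 0.0191 and 0.162% ± 0.0189, and basal and mesenchymal genes 0.0873% ± 0.0274 and 0.137% ± 0.0116. Luminal identity genes stood higher in LTED, at 0.311% ± 0.0350 against 0.252% ± 0.0317, as did cholesterol synthesis genes at 0.177% ± 0.0182 against 0.144% ± 0.0116 and hypoxia genes at 0.0950% ± 0.00629 against 0.0751% ± 0.00737. Steroid metabolism genes, which hold CYP19A1 of the chromosome 15 block, stood at 0.187% ± 0.0287 against 0.0404% ± 0.00737. Fibroblast markers stood at 0.0257% ± 0.00398 against 0.0481% ± 0.0132. All 8 lists passed the exact two-sided permutation test, with adjusted p-values of 0.05 for basal and mesenchymal genes and fibroblast markers and 0.0333 for the others, and unadjusted p-values of 0.02 or 0.01, the smallest possible. With all deposited peaks or with genes within 20 kb, 0 lists passed, and 5 passed without dense windows. The 3 that did not were steroid metabolism (0.000827 points, exact permutation test, adjusted p = 1), fibroblast markers (-0.0091 points, exact permutation test, adjusted p = 0.35) and cholesterol synthesis (0.0413 points, exact permutation test, adjusted p = 0.0857). Without any 1 of the 10 libraries 0 passed, with fewer permutations.

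Starved-only regions again outnumbered LTED-only ones, 1433 to 184, and the total of 1617 was 2715 without replicate 2 of starved CD44low. PRKCA had 10 starved-only regions, ZNF496 and MSI2 6 each, SPATA17 and CAST 5 each, and RGS9, DYSF, LINGO1, USH2A and PLXDC2 4 each. MSI2 encodes an RNA-binding protein of progenitor cells and CAST the calpain inhibitor calpastatin. TGFB2 had 4, IRF1 3, and EGFR, MET, FOXO1, MYC and AXIN2 2 each. Of the 1433, 122 lay in 1 Mb windows where every LTED library had fewer peaks than every MCF7 library, counted on equal-length lists. TGFB2, TFF1, PRKCA, SPATA17 and USH2A lie in such windows. LTED and MCF7 libraries held 6.67 and 16 peaks on average in the window of PRKCA (17:66000001-67000000). In that of SPATA17 (1:217000001-218000000) they held 8 and 19.9. In the dense windows lay 76 of the 1433. MSI2 lies in 1 of them (17:57000001-58000000), covered on average 18.6% in starved cells and 5.63% in LTED. WDR72 with 16, UNC13C with 14 and FAM227B with 9 led the LTED-only regions, 126 of 184 on chromosome 15, and GREB1, ESR1 and NFKB2 had 1 each.

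Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 26740 regions on the deposited lists, with 5105 at an unadjusted p of at most 0.05, and in the simulation it recovered 0% of 2000 all-or-none regions. Adjusted over the list alone, 4 list regions were called in LTED and 15 in starved cells, against 0 over all regions. Beside TGFB2, FOXO1, IRF1, MX2 and NFKB1, the starved calls included markers of other cell types, CD14 and PTPRC of blood and KDR and PECAM1 of endothelium with 1 region each. On equal-length lists 16 and 24 were called over the list alone, against 35 over all regions, with none of these 4 markers among them but POSTN of fibroblasts in starved cells and SPI1 of blood in LTED. On equal-length lists 401 regions were called in LTED and 786 in starved cells. CADPS, a vesicle exocytosis gene, led the starved side with 10, followed by ESRRG, an oestrogen-related receptor gene, with 5. NFASC, STARD13, YPEL2, MARCHF10, MSI2 and BCAS3 had 4 each. Of the 786 starved calls, 85 lay in the dense windows, where CADPS, NFASC, YPEL2, MARCHF10, MSI2 and BCAS3 lie. The window of CADPS (3:62000001-63000000) was covered on average 76.0% in starved cells and 29.5% in LTED. In windows of 1 Mb where every LTED library had fewer peaks than every MCF7 library lay 97 of the 786. Such calls follow blocks of dense peaks and need not mark single genes. List members called in starved cells included TGFB2 and FOXO1 with 2 each, and TFF1, CELSR2, TFAP2C, EPCAM, CLDN4, EGFR and MET with 1 each. Those called in LTED were CYP19A1 with 5, and AGR2, AR, TBX3, ID1, EBP, MKI67, FGFR2, IL6 and HPRT1 with 1 each. Without both LTED libraries of replicate 2, the all-or-none counts on the deposited lists were 2194 for LTED and 1450 for starved cells. The gene-end share was 51.2% ± 2.54 in LTED and 46.8% ± 3.30 in starved cells, which did not pass (exact two-sided permutation p = 0.06). It passed with a 2.5 kb window (p = 0.03, exact), without dense windows (p = 0.01, exact) and without any 1 of 4 libraries, the 3 LTED CD44high ones and replicate 1 of starved CD44high (exact p = 0.05, 0.0167, 0.05 and 0.025). Libraries of one condition were more alike (Jaccard index 0.460 within, 0.378 between, exact one-sided p = 0.05), but not past the threshold without any 1 starved library (exact p = 0.125).

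Both deprived states were set against the same E2 libraries to see whether they share regions. There were 12 regions open in every starved and every LTED library and in no E2 library, where independent lists would share 5.36, and 12 open only with E2, where independent lists would share 0.849. Simulated unchanged groups against these controls shared 0. On equal-length lists 8 were shared among those absent with E2, against 10.4, and 26 among those only with E2, against 2.89. The simulated value leaves out the effects of each state and the independent value leaves out the shared E2 libraries. With E2 CD44high libraries set against starved cells and E2 CD44low libraries against LTED, independent lists would share 1.13 of the regions open only with E2, and 5.51 on equal-length lists, against the same 12 and 26. This value takes no account of regions open in both E2 fractions. Among those absent with E2 there was no excess over independent lists at equal length. AREG, E4F1, HPGD and NRG1 were among the genes of the 12 regions open only with E2 in the deposited lists, and GREB1, SPDEF, MLPH and SOX11 among those of the 26.

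Of the comparisons added after the data were seen, oestrogen-deprived cells (n = 10) against MCF7 with E2 (n = 6) gave 0 calls by Fisher's exact test on deposited lists, with 3121 of 37284 regions at an unadjusted p of at most 0.05, and 24 all-or-none regions (45 without replicate 2 of LTED CD44high, 39 without replicate 2 of starved CD44high). It gave 8 and 26 calls on equal-length lists, where HSD17B7, an enzyme gene of steroid and cholesterol synthesis, was called in deprived cells. LTED (n = 6) against all MCF7 libraries (n = 10) gave 147 regions called in LTED and 131 in MCF7, a total of 278 that was 502 without replicate 2 of LTED CD44high. Of the 147, 124 lay on chromosome 15, led by WDR72 with 16 and UNC13C with 13. The 131 lay near CHRM3, SOX11, AGBL3, MRPL21, SYT1, CEP112 and TFF3 among others, each with 1.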

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

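The tests on chromosome 15, on weak distal peaks, and on depth and other cell types at CDKN2A were chosen only after the result was seen. Every library held peaks on contigs outside chromosomes 1 to 22 and X, which the comparisons above do not use. The lowest library held 20 and the highest 84, and chr14_GL000225v1_random (147 peaks) and chr22_KI270733v1_random (107 peaks) had peaks in all 16 libraries. They stand out only as signal that was not analysed, and no explanation was tested.

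LTED peaks lay densely from 49448562 to 54251827 on chromosome 15, over WDR72, UNC13C, MYO5A and CYP19A1. Longer LTED lists are argued against, since even the shortest LTED list held 15.94 times the share of peaks in the segment of the highest MCF7 library. The covered share of the segment was 31.88 times that of MCF7, but the segment was picked for dense LTED peaks. That choice favours a high ratio, so it cannot decide whether opening of single regulatory sites is the whole pattern. Extra DNA copies of the segment in LTED stay open. Of the 100 kb windows, 100% held over 2 times as many peaks in LTED, but they were picked for dense LTED peaks, so this count decides nothing. Copy number was not measured, and whether aromatase expression differs was not tested.

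The starved libraries had many more regions of their own than the E2 libraries. With equal-length lists, peaks of 500 bp and no dense windows, 216 starved-only and 129 E2-only regions gave a ratio of 1.674, between the bounds set beforehand, so longer and wider starved lists and an effect of oestrogen removal cannot be told apart. Whether more weak distal peaks in the starved libraries are the whole cause was not decided. At equal length the gene-end share of starved-only regions was still only 0.2355 of that of all regions, while E2-only regions stood at 37.5% against 37.1%. Regions that differ were also mostly distal without starved cells, at 16.25% for LTED-only and 18.7% for E2-only regions of LTED against E2. LTED-only regions against starved cells stood at 42.4%. A low share is thus not particular to starved-only regions. Effects of starvation, of depth and of a shared day of preparation stay open, as the labels give no batch.

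CDKN2A and CDKN2B had peaks in 5 of 6 LTED and 0 of 10 MCF7 libraries, while MTAP had its gene-end peak in all 16. Lower depth of the MCF7 libraries is argued against, since the CDKN2A peak lay within the length of the shortest list in 4 LTED libraries and in no MCF7 list. Blood, fibroblast or endothelial cells in the LTED libraries are argued against by 0 of their markers showing the same pattern. Only 1 other run of neighbouring LTED-only regions lay outside chromosome 15 (at AGMO). That rarity cannot decide whether the interval is missing from the DNA of MCF7 but not of LTED. Regions that are present but below the caller's limit in every MCF7 library would give the same run. If the DNA were missing, a derived line could not regain it. A different parental clone or other epithelial cells in LTED would then have to be asked about, and neither was tested.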

How the results depend on the processing

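Settings without dense windows or chromosome 15, with 500 bp peaks, and both comparisons of pooled groups were chosen only after the data were seen. Of the values with 1 library left out, 247 kept their side of the threshold or stayed near the reported value, 56 moved, 10 no longer passed, 5 newly passed and 2 reversed. Under other alternatives 91 stayed, 81 moved, 3 no longer passed, 3 newly passed and 1 reversed. Where values moved below, the cause was not tested unless it is named.

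For CD44 the all-or-none count was 1 with at most 1 exception and 1 without both LTED libraries of replicate 2 (0 to 1 with 1 library left out). For starved MCF7 against E2 it was 405 with equal-length lists, 2203 with 50% coverage, 6889 with 500 bp bins, 348 with equal-length lists without dense windows, 345 with 500 bp peaks in addition and 4577 with at most 1 exception (1216 to 2212 with 1 library left out). Fewer libraries or a looser rule raise such counts by construction, and bins split regions.

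For LTED against E2 the all-or-none count was 190 with a score of at least 100, 150 with 50% coverage, 1747 with bins, 276 without dense windows, 1361 with 1 exception, 3028 without both LTED libraries of replicate 2 and 260 without chromosome 15 (439 to 768). The called count was 1099 with equal-length lists, 848 without dense windows, 288 with 500 bp peaks and 3028 without replicate 2 of LTED (0 to 768, where 768 is without LTED CD44high replicate 2). For LTED against starved MCF7 the all-or-none count was 960 with a score of at least 100, 8098 with bins, 898 and 870 with equal-length lists without dense windows and with 500 bp peaks, 5105 with 1 exception and 3644 without replicate 2 of LTED (1722 to 2715). Its called count was 1187, 898 and 870 on the equal-length settings in that order.

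For LTED against all MCF7, called and all-or-none counts were both 117 with a score of at least 100, 1248 with bins, 163 without dense windows and 1569 without replicate 2 of LTED (283 to 502 for each). Calls were 708 with equal-length lists, 0 with 50% coverage (72 all-or-none), 502 without dense windows at equal length (168) and 487 with 500 bp peaks (156), and 854 were all-or-none with 1 exception. For deprived cells against E2, calls were 34, 41 and 42 on the equal-length settings and 195 without replicate 2 of LTED. All-or-none counts were 4 with a score of at least 100, 79 with bins, 41, 42, 134 with 1 exception and 195 (25 to 45).

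Within conditions, CD44 counts were 21 (score of at least 100), 227 (equal length), 775 (bins), 175 and 176 (no dense windows, 500 bp peaks) in LTED, 159 to 2331 with 1 library left out. In E2 cells they were 250, 2397, 187 and 192 (989 to 3049), and in starved cells 2919, 1259, 22897, 1016 and 1068 (10656 to 16733).

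Gene-end share differences ran from 0.699 to 2.622 for CD44, from -5.809 to -3.252 for starved against E2, from -1.108 to 0.395 for LTED against E2 and from 2.852 to 5.409 for LTED against starved with 1 library left out. For LTED against E2 the sign reversed to 0.832 without dense windows, and LTED against starved passed at 4.662 with a 2.5 kb window and at 7.456 without dense windows. Similarity with 1 library left out ran from 0.0541 to 0.0774 for LTED against E2 and from 0.0588 to 0.1033 for LTED against starved. The number of gene lists that passed was 0 for CD44 within 20 kb and without dense windows (0 to 1), 0 for starved against E2 with all peaks and within 20 kb (0 to 0), 8 for LTED against E2 with all peaks and 2 without dense windows (2 to 4), and 0, 0 and 5 for LTED against starved with all peaks, within 20 kb and without dense windows (0 to 0).

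The labels do not pair replicate numbers. All 8 same-numbered pairs of 1 condition had positive correlations of their deviations (0.0275 to 0.160), and 16 of 16 libraries correlated best with their own number in the other fraction, a hint from the data only. With a replicate block, 0 lists passed in any of the 4 comparisons. In the comparisons with starved cells none could pass, since 36 permutations give no exact p under 0.0556. With 256 permutations for CD44 and 216 for LTED against E2, several lists would have to tie at the smallest p to pass the adjustment. These 0 lists thus do not show that the results fail under pairing. Similarity was -0.0055 for CD44, which passed under the block (exact one-sided p = 0.0313). It was 0.1279 for starved against E2 and 0.1229 for LTED against starved (exact p = 0.0556 for each, the smallest that 36 permutations can give). The gene-end share of starved against E2 was -4.734 (exact p = 0.0556, again the smallest possible). The blocked region test had 0 testable regions in the comparisons with starved cells and gives no value there. Motif alternatives were not run. Depth is unknown and limits every count of absent peaks.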

Other observations

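The counts of 100 splits were planned, and those of all splits, those with same-numbered fractions kept together and the count of separated windows were chosen only after the result was seen. Splits of single libraries treat each library as an independent unit, which the labels do not state. On that footing chance in the assignment of libraries is argued against for starved MCF7 against E2. There 1 of 100 splits, the real one, gave 1085 all-or-none regions and the highest other gave 221. The same held for LTED against E2 (1 of 100, 418 against 83) and LTED against all MCF7 (1 of 100, 278 against 17). The draws missed larger splits. Over all 210, 462 and 8008 splits the highest others were 270, 299 and 144, and still only the real split reached its count. For LTED against starved the draw gave 1 of 100 (1617 against 547), but of all 210 splits one gave 1574. It put the short LTED lists of replicate 2 with the starved ones, so the deposited count hardly stands apart from it. On equal-length lists the highest of 210 was 231 against 1187. For deprived cells against E2 the draw gave 1 of 100 (24 against 9), while 27 of all 8008 splits gave as many, the highest with 278 being LTED against all MCF7. For CD44, 100 of 100 splits gave at least the 0 of the real one (highest other 3, over all 6435 splits 140). No split can give fewer than 0, so this count says nothing about chance. Within LTED 7 of 10 splits gave as many as 80 (highest other 2386) and within E2 cells 4 of 10 as many as 490 (highest other 846), and 10 splits cannot give a share under 0.1. The split of LTED with 2386 put both short lists of replicate 2 on one side, so it follows list length. On equal-length lists the highest other split was 245 against 227 in LTED and 321 against 250 in E2 cells.

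If fractions of one number shared a culture, the splits that keep them together are the better guide. The highest of 10 such splits was 224 against 418 for LTED against E2, 221 against 1085 for starved against E2 and 1574 against 1617 for LTED against starved, and of 56 splits 85 against 278 for LTED against all MCF7. On equal-length lists the values were 9 against 427, 107 against 405, 231 against 1187 and 34 against 270. Shares under 0.1 cannot be reached with 10.

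Peaks were counted in windows of 1 Mb on equal-length lists. In the windows with enough peaks (1214), every LTED library lay above every MCF7 library in 47 and below in 44, where chance gives 0.0125% each way. With a neighbour of the same kind were 20 and 15, against means of 2.02 and 1.77 when shuffled (highest 12 and 8). On chromosome 7 lay 15 of the 47, between 7:11000001 and 7:31000000, and 14 of the 44, between 7:42000001 and 7:144000000. AGR2 and IL6 lay in windows above, TGFB2, TFF1 and TFF3 in windows below.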
